A study of Homo sapiens with 2 samples.

How the data were processed

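Poly(A)-selected mRNA was sequenced from Huh7 cells, an established human hepatocellular carcinoma line, after 48 h in medium with DMSO (the solvent control) or with homochlorcyclizine dihydrochloride, an antihistamine that blocks histamine H1 receptors. The dose of the compound is not given in the sources used here. The labels assign 1 library to each group and name no replicate, so 2 libraries were compared.

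The authors deposited 1 table of raw counts per gene for both libraries, whose column names are tied to the samples in the labels' descriptions, and 1 table of FPKM values, which scale counts to gene length and library total, for each library. Per the submitters' processing notes the genome build was hg38. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The count table holds 19927 gene symbols, of which 19802 matched protein-coding genes of the RefSeq annotation of GRCh38.p14. Non-coding RNAs as a class were therefore not covered. Symbols without such a match were kept, since genes were filtered by level only. The lengths implied by the deposited counts and FPKM of the 13 mitochondrial genes were within 1 base of the RefSeq lengths. In the 14778 genes with counts in both libraries, the ratio of the deposited FPKM values differed from the ratio of counts scaled to library totals by at most 3.13e-05%, so the FPKM tables hold the same measurement as the counts and were used only as an alternative scale. Of the symbols, 19 end in _1 and were kept as separate rows.

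The total was 38133894 counts in the DMSO library and 40791119 in the homochlorcyclizine library. Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, and ratios, intervals and lists were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The log2 ratio of each gene was taken between TMM-scaled library-size-normalised counts (CPM) with a prior count of 1. Each ratio has an exact 95% interval (Clopper-Pearson, conditional on the gene's summed count). PCR copies are not independent molecules and no second culture was sequenced, so intervals and floors cover counting error only. At the filter of 1 CPM the interval spans about 1.57-fold to either side of the ratio, and at 5 CPM about 1.22-fold. A count of 0 allows a level of up to 3 counts, which is 0.0785 CPM in the DMSO library and 0.0737 CPM in the homochlorcyclizine library.

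With 1 library per group no test between conditions can be made, so no p-value is given. Genes were described by a rule of size. A gene was counted as higher or lower when its ratio was at least 2-fold and its counting interval excluded 1, among the 12353 genes with a mean of at least 1 CPM over both libraries. A total of 44 gene lists was written before the data were examined, 4 of them markers of other cell types, and 41 lists had at least 5 measured members. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5. These percentiles describe the 2 libraries. Genes of a pathway vary together from culture to culture and randomly drawn genes do not, so a percentile is not a p-value. Chance alone would place about 2.1 of the 41 lists apart if genes varied independently. Of 890 listed genes in the data, 36 were in more than 1 list, so the lists are not separate evidence. Among them are GDF15 (ATF4 and p53 targets) and DDIT4 (ATF4 and HIF targets).

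The named genes follow a rule fixed at the same time. They are the 12 higher and 12 lower genes with the largest change among those with a mean of at least 5 CPM, ranked by the interval bound nearest to 1. To these come up to 4 members of each described list with the largest absolute log2 ratio, and 20 genes chosen whatever their values. Some genes that this rule takes are not reported here. Any other gene is said to have been chosen after its values were seen, which also holds for the gene copies CBS and SULT1A3. Gene coordinates are those of RefSeq on GRCh38.p14, the same assembly as hg38, matched by symbol, and count from 1.

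The size rule was tested on simulated data drawn from these libraries' means with Poisson error alone. It recovered 100% of 200 genes changed 3-fold and 51% of 200 changed exactly 2-fold, and made 0 calls in a pair of 12344 unchanged genes, with 1 false call in the 2-fold run. The simulated 95% intervals held the true ratio in 95.4% of unchanged genes, and in 27.3% once a coefficient of variation of 20% between cultures was assumed. For the list rule, 200 lists of 25 genes were drawn at random from a simulated unchanged pair with that variation of 20%. Of these lists, 2.5% stood apart, and random draws of independent genes give a low share by construction. The share does not measure how often lists of genes that vary together would stand apart. The alternatives tried were scaling by total counts, DESeq2 1.42.0 size factors or upper-quartile factors, a prior count of 5, the deposited FPKM with a pseudocount of 1 or 0.1, no filter or a filter of 5 CPM, ratios of 1.5 or 3, whole intervals beyond a ratio of 2, list means, lists without the member that moved most, and unmatched random lists. Removal of the trend over GC content and length was added later, with GC content from GENCODE release 29 transcripts. Figures were drawn with matplotlib 3.10.9.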

Results

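The transcriptome of Huh7 hepatocellular carcinoma cells was compared between 1 culture kept for 48 h with DMSO and 1 culture kept for 48 h with homochlorcyclizine, a piperazine-type antihistamine. The question was which genes differ in expression after treatment with this compound. The DMSO library held 38133894 counts over 15312 detected genes and the homochlorcyclizine library 40791119 counts over 15443 genes. The 10 most abundant genes took 5.92% of the counts in the DMSO library and 6.12% in the treated library. Each group is 1 library, so every difference below is a difference between these 2 libraries with no replicate check. Every interval is a 95% counting interval unless it is called a bootstrap interval.

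Of 12353 genes with a mean of at least 1 CPM, 718 (5.81%) were at least 2-fold higher and 630 (5.10%) at least 2-fold lower in the homochlorcyclizine library. Lists of cell division genes stood below the random lists, and lists of ATF4 and NRF2 targets, lipid synthesis and lysosome genes stood above them. Across genes, log2 CPM correlated between the libraries with Pearson's r of 0.959, where genes are not independent replicates, and the median absolute log2 ratio was 0.34. Spread between cultures was not measured. In simulated pairs of unchanged libraries, an assumed coefficient of variation of 10% between cultures gave 3 genes past the same rule. One of 20% gave 234 and one of 30% gave 1371, against 1348 observed. Genes varied independently of each other in these simulations.

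**Figure D1:**
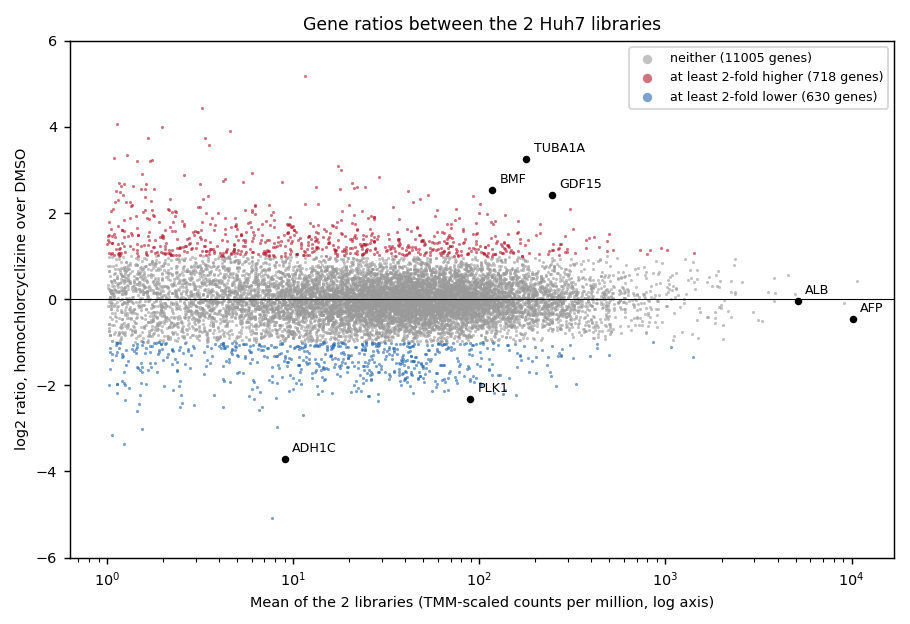
Log2 ratio of each of the 12353 genes (vertical axis, homochlorcyclizine over DMSO) against its mean level in TMM-scaled CPM (horizontal log axis), 1 point per gene and 1 library per group. The 718 genes at least 2-fold higher are red and the 630 at least 2-fold lower are blue, and TUBA1A, BMF, GDF15, ALB, AFP, PLK1 and ADH1C are labelled.

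Among genes with a mean of at least 5 CPM, TUBA1A, an alpha-tubulin (chromosome 12, 49184795 to 49189080), was 9.53-fold higher in the homochlorcyclizine library, at 324 against 33.9 CPM (interval 9.0 to 10.1), where reads may be split among similar tubulin genes. ENO2, the neuronal enolase (chromosome 12, 6914580 to 6923697), was 8.58-fold higher (7.19 to 10.3). TMPRSS9, a membrane serine protease, was 8.01-fold higher (6.77 to 9.53). IGFBP1, a liver-made binding protein of insulin-like growth factors (chromosome 7, 45888488 to 45893660), was 7.16-fold higher (6.31 to 8.16). BMF, a pro-apoptotic member of the BCL2 family (chromosome 15, 40087890 to 40108879), was at 200 against 34.7 CPM, 5.76-fold higher (5.44 to 6.11). The nuclear receptors NR1D1 and RORA of the circadian clock were 6.47-fold (5.60 to 7.51) and 6.68-fold (5.32 to 8.47) higher. CLTRN, CIDEC (a lipid droplet protein), DEPP1 and LTBP1, which binds latent TGF-beta, were between 6.04-fold and 7.69-fold higher. The first gene by rank was LOC102724560, with 918 counts against 23. It is a near-identical copy of CBS, reads can be split between them, and the summed counts of both copies gave a ratio of 0.980 (0.927 to 1.04).

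Among the lower genes, ADH1C, an alcohol dehydrogenase (chromosome 4, 99336497 to 99352746), was at 1.25 against 16.8 CPM, a ratio of 0.0746 (0.0549 to 0.0993). AGXT2, a mitochondrial aminotransferase, had a ratio of 0.126 (0.0972 to 0.160). VDR, the vitamin D receptor (chromosome 12, 47841537 to 47904994), was at 3.02 against 19.6 CPM, a ratio of 0.154 (0.127 to 0.187). TFEC, a transcription factor of the MITF family, had a ratio of 0.166 (0.129 to 0.213) and CD300LF one of 0.175 (0.136 to 0.221). The mitotic genes PLK1, CENPE, CDC20, NCAPG and KIF14 had ratios between 0.193 and 0.219. The linker histone H1-2 had a ratio of 0.214 (0.204 to 0.224). SULT1A4 had the lowest ratio, 0.0279 (0.0162 to 0.0451), and may share reads with its near-identical copy SULT1A3. SULT1A3 was higher, with 154 counts against 35, and the summed counts of both gave a ratio of 0.265 (0.222 to 0.314).

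Genes of cell division were lower throughout. Of 32 measured genes of G2 phase and mitosis, 31 were at least 2-fold lower and the other 1 was below a ratio of 1. The list's median log2 ratio was -1.81, and its median lay below all 10000 random lists, whose central 95% ran from -0.20 to 0.17. CENPE, a kinetochore motor, was at 9.26 against 47.9 CPM. PLK1, the mitotic polo-like kinase (chromosome 16, 23678889 to 23690367), was at 29.7 against 149 CPM, and CDC20, an activator of the anaphase-promoting complex, at 47.8 against 220 CPM. KIF20A, a cytokinesis motor, was at 15.8 against 71.8 CPM. The proliferation marker MKI67 had a ratio of 0.395 (0.382 to 0.409).

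Of 30 measured genes of DNA replication and the G1/S transition, 28 were at least 2-fold lower and all 30 were below a ratio of 1, with a median log2 ratio of -1.42, also below all random lists. MCM10, a replication initiation factor, was at 22.9 against 94.4 CPM, and RRM2, the small subunit of ribonucleotide reductase, at 103 against 416 CPM. GINS2 of the replicative helicase was at 17.0 against 65.0 CPM and UHRF1, which maintains DNA methylation, at 21.1 against 79.6 CPM. Among 11 measured replication-dependent histones, whose mRNAs mostly lack the poly(A) tail used for selection, 2 were at least 2-fold lower, H1-2 and H2BC11, and the median of -0.23 lay within the random lists at percentile 11.8. The histone list lay below the random lists with no filter (-0.66), with a filter of 5 CPM (-0.43) and as a mean (-0.47). The cell cycle inhibitor CDKN1A was 1.67-fold higher (1.59 to 1.76), under the 2-fold rule.

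Growth-related genes of ribosome production were lower as well. Of 24 measured MYC and ribosome biogenesis genes, 3 were at least 2-fold lower, 22 were below a ratio of 1, and the median log2 ratio of -0.70 lay below all random lists. MYC itself, chosen after its values were seen, was not lower, at 278 against 256 CPM (ratio 1.09, 1.06 to 1.12). ODC1, the first enzyme of polyamine synthesis, had a ratio of 0.484, SRM (spermidine synthase) one of 0.487, LYAR one of 0.492 and BOP1, a factor of large ribosomal subunit maturation, one of 0.513. The 32 ribosomal proteins had no member past 2-fold and a median of 0.12, within the random lists at percentile 88.3. RPS2 was lowest among them with a ratio of 0.755 (0.747 to 0.762).

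Sterol synthesis genes were higher. Of 26 measured genes of cholesterol biosynthesis and SREBP2 targets, 8 were at least 2-fold higher, none was 2-fold lower and 25 were above a ratio of 1, with a median log2 ratio of 0.72, above all random lists. TM7SF2, a sterol reductase, was 2.40-fold higher (2.31 to 2.49), SC5D 2.24-fold (2.17 to 2.30), DHCR7, the last enzyme of one branch of the pathway, 2.20-fold (2.16 to 2.24) and CYP51A1, the lanosterol demethylase, 2.20-fold (2.17 to 2.23). SQLE (1.55-fold, 1.53 to 1.58), INSIG1 (1.74-fold, 1.70 to 1.79) and EBP (1.48-fold, 1.45 to 1.51) were above 1 and under the 2-fold rule.

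Fatty acid and triglyceride synthesis genes were also higher, with 3 of 19 at least 2-fold higher, none 2-fold lower, and a median log2 ratio of 0.62 above all random lists. ACSS2, an acetyl-CoA synthetase, was at 482 against 156 CPM, LPIN1 at 143 against 49.7 CPM and PNPLA3 at 116 against 46.7 CPM. FASN, fatty acid synthase, was 1.90-fold higher (1.88 to 1.92). Fatty acid oxidation genes went both ways. Of 16 measured, 2 were at least 2-fold higher, 1 was at least 2-fold lower and 10 were below a ratio of 1. CPT1A, the carnitine transferase that admits fatty acids to mitochondria, was 2.96-fold higher (2.84 to 3.09). The lipid droplet protein PLIN2 was 2.60-fold higher (2.53 to 2.66). The peroxisomal enzyme EHHADH had a ratio of 0.576, under the 2-fold rule. The list's median of -0.27 lay within the random lists at percentile 2.76. Of 10 genes of cholesterol efflux and LXR response, APOE was 2.28-fold higher (2.25 to 2.32), the only one past 2-fold, and NR1H2, APOC1 and SMPDL3A had log2 ratios of 0.46, 0.41 and 0.37. The median was 0.19, at percentile 90.2.

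Lysosomal genes were higher as a group. Of 30 measured lysosomal hydrolases, membrane proteins and proton pump subunits, 8 were at least 2-fold higher, none was 2-fold lower and 26 were above a ratio of 1, with a median log2 ratio of 0.74 above all random lists. The tripeptidyl peptidase TPP1 was 2.80-fold higher (2.70 to 2.90), the sialidase NEU1 2.42-fold (2.35 to 2.5), CTSA 2.23-fold (2.17 to 2.30) and the protease CTSD 2.19-fold (2.15 to 2.24). NPC1, the lysosomal cholesterol exporter (chromosome 18, 23506184 to 23586506), was 2.04-fold higher (1.93 to 2.16). Of 26 autophagy genes, 4 were at least 2-fold higher and none 2-fold lower, with a median of 0.50 above all random lists. These 4 were BNIP3L, a mitophagy receptor, at 2.56-fold, the initiating kinase ULK1 at 2.34-fold, the receptor OPTN at 2.20-fold and GABARAPL1 at 2.09-fold.

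Genes of the integrated stress response were higher. Of 33 measured ATF4 pathway genes, 12 were at least 2-fold higher, none was 2-fold lower and 31 were above a ratio of 1, with a median log2 ratio of 0.73 above all random lists. The stress cytokine GDF15 was at 414 against 77.3 CPM, 5.35-fold higher (5.15 to 5.57), and the transcription factor ATF3 5.02-fold (4.60 to 5.48). The lipoprotein receptor VLDLR was 3.91-fold higher (3.46 to 4.42) and CHAC1, which degrades glutathione, 3.73-fold (3.36 to 4.15). TRIB3 was 2.66-fold higher (2.59 to 2.73) and DDIT3, which encodes CHOP, 2.20-fold (1.97 to 2.46). ASNS, asparagine synthetase, was 1.67-fold higher (1.62 to 1.72). NRF2 targets were higher too, with 7 of 24 past 2-fold, none 2-fold lower and a median of 0.45 above all random lists. AKR1B10 was 8.01-fold higher at a low level (2.73 against 0.340 CPM, 4.50 to 15.5) and HMOX1, heme oxygenase, 2.42-fold (2.30 to 2.54). The paralogs AKR1C1 and AKR1C2, between which reads may be split, were 3.51-fold higher when summed (3.40 to 3.62).

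Chaperones did not move with the ATF4 genes. Of 23 endoplasmic reticulum chaperone and unfolded protein response genes, 4 were at least 2-fold lower and 1 was at least 2-fold higher. In all, 12 were below a ratio of 1 and 11 above it. SDF2L1 had a ratio of 0.370 (0.344 to 0.399), PDIA4, a protein disulfide isomerase, one of 0.404 (0.392 to 0.416) and CRELD2 one of 0.431, while the stress sensor ERN1 was 2.60-fold higher (2.36 to 2.87). Other members were chosen after their values were seen. The chaperones HSP90B1, HSPA5 and CALR had ratios of 0.466, 0.578 and 0.609, while CANX and DNAJB9 were above 1. The stress sensor EIF2AK3 and the transcription factor CREB3L3 were 1.82-fold and 1.45-fold higher. The list median therefore pools members that moved in opposite directions. The list's median was -0.21, at percentile 4.09 within the random lists, and 0.03 with the GC and length trend removed. Of 14 cytosolic heat shock genes none passed 2-fold and 11 were below a ratio of 1, with a median of -0.46 at percentile 0.17. HSPA4L, HSP90AA1, HSPD1 and HSPE1 had ratios of 0.513, 0.530, 0.536 and 0.545. All 5 measured genes of the metallothionein list were below a ratio of 1 and 4 were at least 2-fold lower. MT1X was at 0.884 against 4.95 CPM, MT1E at 2.04 against 10.3 CPM, MT1F at 2.43 against 10.9 CPM and MT2A at 4.27 against 16.5 CPM. These are similar paralogs among which reads may be split, and the list's median of -2.15 lay below all random lists.

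**Figure D2:**
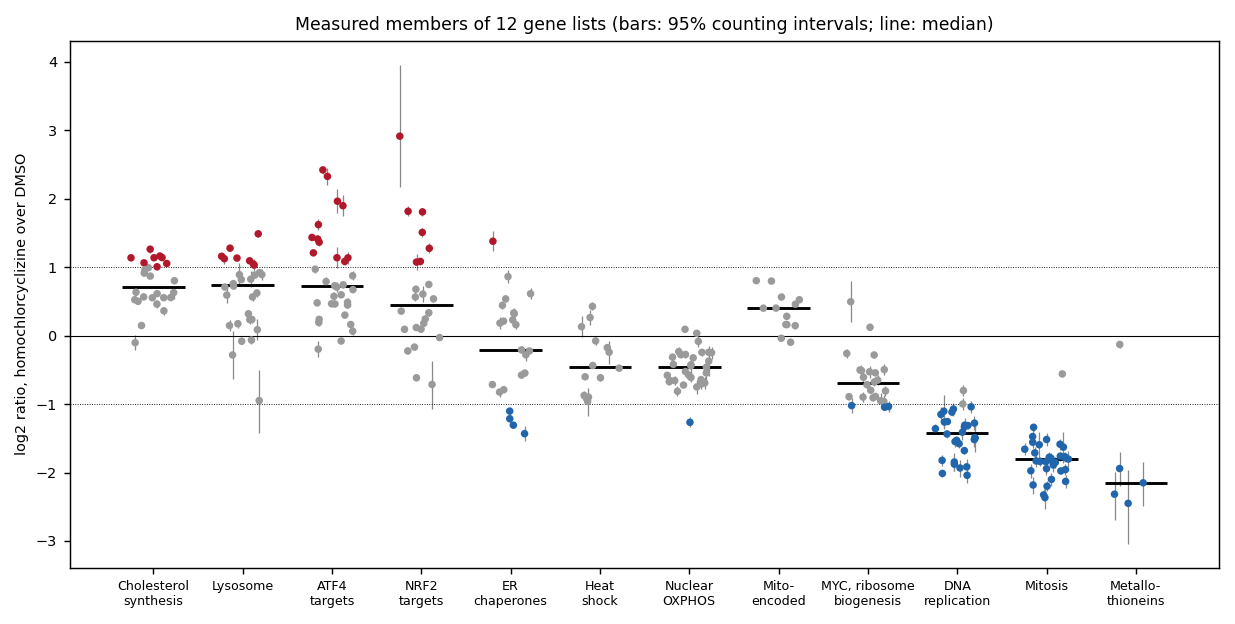
Log2 ratios (vertical axis, homochlorcyclizine over DMSO) of the measured members of 12 gene lists (horizontal axis), 1 point per gene with its 95% counting interval as a bar and the list median as a black line. Points at least 2-fold higher are red and at least 2-fold lower blue, and dotted lines mark 2-fold. In the mitosis list 31 of 32 points are blue and in the cholesterol list 8 of 26 are red.

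Among 26 genes of the BCL2 family and caspases, 5 were at least 2-fold higher and 1 was 2-fold lower. The higher ones include the pro-apoptotic BMF, BOK (3.74-fold, 2.80 to 5.06) and BBC3, which encodes PUMA (3.31-fold, 2.78 to 3.95). BIRC5, survivin, which is also a mitotic gene, had a ratio of 0.260 (0.244 to 0.276). The median of 0.05 lay within the random lists at percentile 70.9, and was -0.04 with a filter of 5 CPM. The mean of 0.27 lay above the means of the random lists, at percentile 99.05. Of 22 p53 targets, 3 were at least 2-fold higher (GDF15, BBC3 and BTG2) and AEN was 2-fold lower. Their median log2 ratio of -0.03 and mean of 0.28 differ in sign, and the median lay at percentile 44.0. Of 19 ferroptosis regulators 3 were 2-fold higher and 2 were 2-fold lower. The 3 higher genes are also members of the ATF4 list. CHAC1 and SLC3A2, a subunit of the cystine transporter, were higher, while the lipoxygenase ALOX15 had a ratio of 0.381 (0.30 to 0.482) and DHODH one of 0.461. The median of 0.24 was at percentile 97.0.

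Most respiratory chain mRNAs differed by genome. Of 31 nuclear-encoded subunits, 29 were below a ratio of 1 and 1, ATP5MC1 (ratio 0.415), was 2-fold lower, with a median log2 ratio of -0.46 below all random lists. CYC1, NDUFB3 and ATP5F1A had ratios of 0.569, 0.594 and 0.606. Of the 13 mitochondrially encoded genes, some of which share an mRNA, 11 were above a ratio of 1 and none passed 2-fold. Their median was 0.40 at percentile 99.2. ND5 and ND6, subunits of complex I, were each 1.74-fold higher, ND4 1.48-fold and ND4L 1.44-fold. Members that went against their list were chosen after their values were seen. The mitochondrially encoded COX1 (8815 against 9432 CPM) and COX3 had ratios of 0.935 and 0.973. The nuclear-encoded COX4I1 and COX5A had ratios of 1.02 and 1.07. The mitochondrial genes took 2.99% of counts in the DMSO library and 3.46% in the treated library.

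Liver functions were mixed. Of 28 measured plasma protein genes 1 was at least 2-fold lower, haptoglobin (HP), at 0.442 against 2.51 CPM. PLG, KNG1 and APOH had ratios of 0.509, 0.557 and 0.592. The list's median of 0.06 and mean of -0.08 differ in sign, and the median lay at percentile 74.9. Albumin (ALB, chromosome 4, 73404287 to 73421482) was at 5059 against 5244 CPM, a ratio of 0.965 (0.959 to 0.971), and alpha-fetoprotein (AFP, chromosome 4, 73436221 to 73456174) at 8540 against 11781 CPM, a ratio of 0.725 (0.722 to 0.728). Of 14 oncofetal and carcinoma markers 3 were 2-fold higher (AKR1B10, IGF2 and SPINK1) and PEG10 was 2-fold lower. Their median of -0.12 was at percentile 19.5, with a mean of 0.18. Of 16 liver transcription factors and nuclear receptors only NR0B2, the bile acid-induced repressor SHP, passed 2-fold (3.08-fold higher, 2.78 to 3.42), and the median was 0.00 at percentile 55.5. NR1H4, FOXA1 and ONECUT1 had log2 ratios of -0.50, -0.45 and -0.44.

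Of 14 bile acid genes, 6 were at least 2-fold higher and none 2-fold lower, with a median of 0.65 at percentile 99.9. Besides NR0B2, the uptake transporters SLCO1B3 (2.66-fold, 1.79 to 4.02) and SLCO1B1 (2.29-fold, 1.67 to 3.17) and the conjugating enzyme BAAT (2.19-fold, 1.90 to 2.53) were higher. CYP7A1, the rate-limiting enzyme of bile acid synthesis, and the drug-metabolising CYP3A4 had 0 counts in both libraries, which allows up to 0.0785 CPM in the DMSO and 0.0737 CPM in the treated library. Of 21 xenobiotic metabolism genes, 8 were at least 2-fold higher and none 2-fold lower, with a median of 0.30 at percentile 97.0, within the random lists. The list lay above the random lists under 5 alternatives, among them its mean (0.59) and removal of the GC and length trend (0.43). CYP1A1 was at 326 against 97.0 CPM, 3.36-fold higher (3.24 to 3.49), and CYP2B6 at 313 against 107 CPM, 2.92-fold higher (2.82 to 3.02). UGT2B15 and CYP2E1 were 6.57-fold (3.57 to 13.2) and 3.59-fold (2.08 to 6.53) higher at levels under 3 CPM. Of 16 gluconeogenesis and urea cycle genes 3 were 2-fold lower, all at levels under 3 CPM. TDO2 (tryptophan dioxygenase), CPS1 and OTC had ratios of 0.188, 0.247 and 0.245, while ASS1 was 1.89-fold higher (1.82 to 1.96). The median of that list was -0.20 at percentile 9.72, and 0.14 with a filter of 5 CPM. Its mean of -0.44 (percentile 0.6) and its median of -0.39 with the GC and length trend removed (percentile 1.04) lay below the random lists.

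Several signalling lists stood above the random lists. The immediate-early list had 5 of 19 genes at least 2-fold higher, none 2-fold lower and a median of 0.70, with the phosphatase DUSP5 3.0-fold higher (2.77 to 3.25), NR4A1 2.87-fold, KLF4 2.29-fold and JUND 2.16-fold. The YAP and TGF-beta list had 4 of 14 genes 2-fold higher, none 2-fold lower and a median of 0.70 at percentile 99.99. THBS1 was 4.29-fold higher (4.02 to 4.59), TGFBI 4.03-fold (3.81 to 4.27) and ANKRD1 3.28-fold. Of 12 mesenchymal and matrix genes 11 were above a ratio of 1 and the integrin ITGAV was 2-fold higher (2.28-fold, 2.21 to 2.35), with ITGA5, VIM and FN1 between 1.81-fold and 1.91-fold and a median of 0.52 at percentile 99.85. With no filter that list lay within the random lists, at 0.41 and percentile 97.1. Of 22 growth factor receptor and insulin signalling genes 5 were 2-fold higher and none 2-fold lower, with a median of 0.44 at percentile 99.98. IGFBP1 led that list, IRS2 was 3.32-fold higher (2.79 to 3.96), FOXO3 2.13-fold and INSR, the insulin receptor, 2.08-fold.

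All 18 measured HIF targets were above a ratio of 1 and 2 passed 2-fold, DDIT4 (3.08-fold, 2.90 to 3.26) and KDM3A (2.24-fold, 2.13 to 2.35), with VEGFA 1.92-fold and INSIG2 1.82-fold higher. The median was 0.69, above all random lists. Of 18 interferon-stimulated genes, OAS1 (3.95-fold, 3.75 to 4.17) and OAS3 (2.35-fold, 2.26 to 2.45) were 2-fold higher, IFIT1 was 2-fold lower at a low level (0.737 against 1.52 CPM), and IFI6 was just under 2-fold higher (1.66 to 2.41). The median of 0.70 was at percentile 99.99, with a mean of 0.43 and 4 of the 18 genes below a ratio of 1. Of 16 NF-kB, chemokine and acute phase genes 4 were 2-fold higher and none 2-fold lower, with a median of 0.32 at percentile 98.9. These were CXCL8 (2.64-fold), RELB (2.51-fold), ICAM1 (2.41-fold) and TNFAIP3 (2.04-fold). Of 20 glycolysis genes 3 were 2-fold higher, ENO2, PFKFB4 (2.88-fold) and the lactate exporter SLC16A3 (2.21-fold). The median of -0.05 and mean of 0.22 differ in sign, and the median lay at percentile 33.9. Of 12 Wnt targets LGR5 alone passed 2-fold (3.62-fold higher, 3.31 to 3.96), and the median was 0.14 at percentile 79.0. Of 13 iron genes, TFR2 (5.63-fold, 3.18 to 10.7, at a low level) and HMOX1 were 2-fold higher, with a median of 0.12 at percentile 77.2.

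The known target of the compound, the histamine receptor HRH1, had 0 counts in the DMSO library and 6 in the treated library, 0.147 CPM, below the level analysed. Of the histamine list 5 genes were measured and none passed 2-fold. ALDH2, the histamine-methylating HNMT, MAOB and SLC29A4 had ratios of 0.712, 0.733, 0.735 and 1.08, and the list's median was -0.44 at percentile 4.33. Of 7 sigma-receptor, emopamil-binding and cholinergic genes, acetylcholinesterase (ACHE) was 4.25-fold higher (3.36 to 5.43) and TMEM97, the sigma-2 receptor, 2.29-fold higher (2.23 to 2.35), with a median of 0.31 at percentile 92.2.

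Of 24 housekeeping reference genes none passed 2-fold, and the median was -0.20 at percentile 3.92. GAPDH had a ratio of 0.811 (0.804 to 0.817) and ACTB one of 0.720 (0.715 to 0.726). SDHA and HPRT1 had log2 ratios of -0.66 and -0.63. Markers of other cell types gave few measured genes. The fibroblast and leukocyte lists each had 4 measured genes and none past 2-fold, with lysozyme (LYZ) of the leukocyte list at 527 against 446 CPM. The endothelial list had 2 measured genes, with PECAM1 2-fold lower at 5.63 against 11.7 CPM. Of 6 cholangiocyte and epithelial markers none passed 2-fold, and the median was 0.23 at percentile 83.0.

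**Figure D3:**
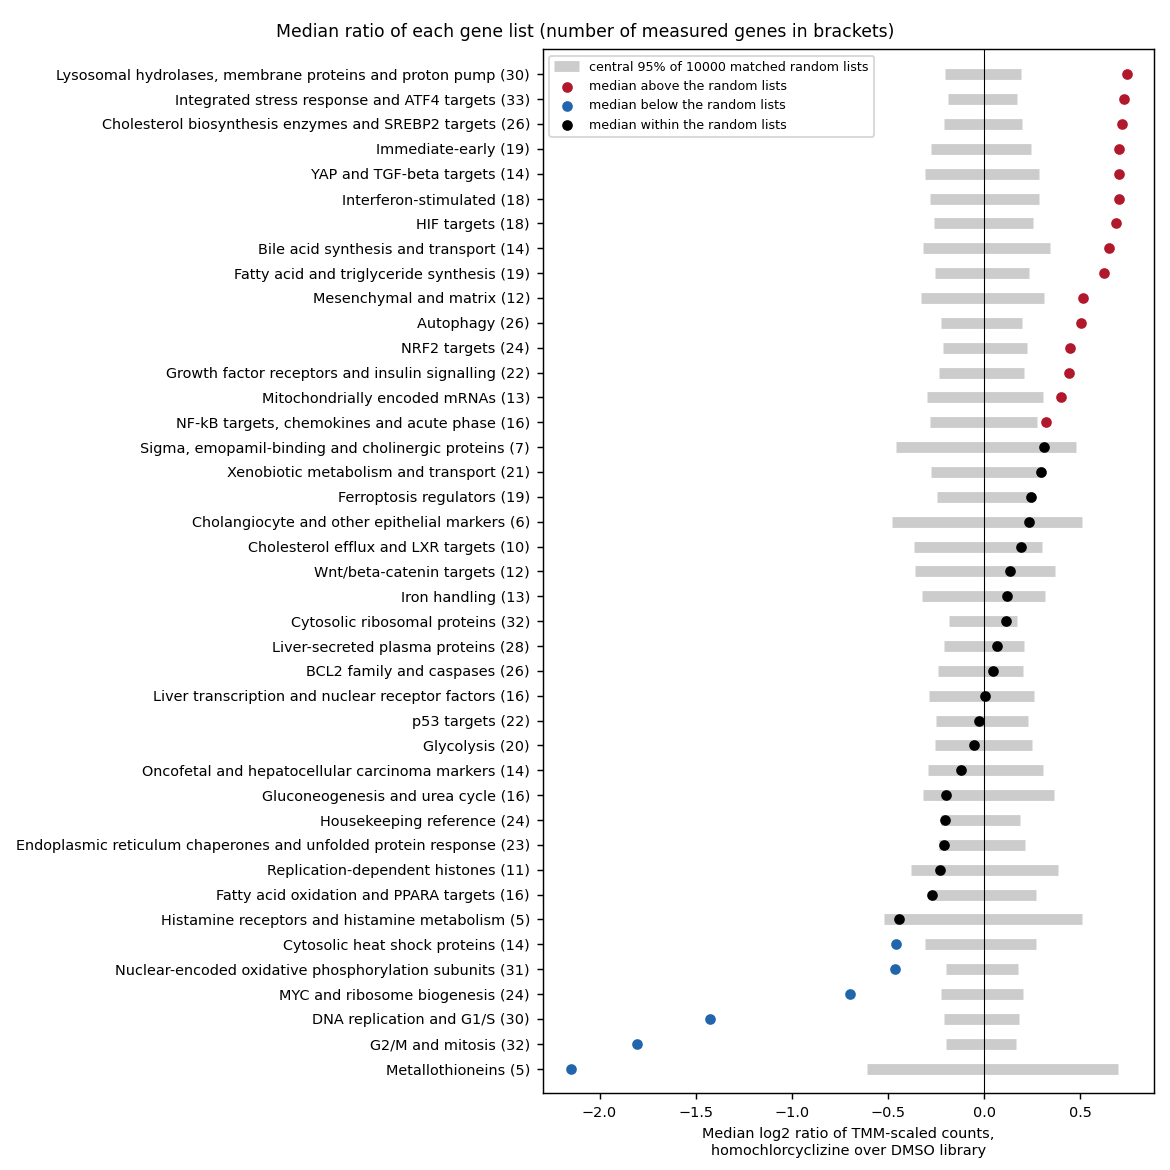
Median log2 ratio (horizontal axis, homochlorcyclizine over DMSO) of each of 41 gene lists (vertical axis, measured genes in brackets) as points, with the central 95% of 10000 expression-matched random lists as grey bars. Of the lists, 15 lie above the random lists (red) and 6 below (blue), and 20 lie within (black).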

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

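Removal of the GC and length trend and leaving out the cell cycle lists were chosen only after the results had been seen. No paired analysis was possible because each group is 1 library. No replicate could be left out for the same reason. The main counts were 718 genes higher and 630 lower. They were 706 and 639 with total counts, 725 and 623 with DESeq2 size factors, 756 and 589 with upper-quartile factors, and these scalings moved the median of all genes by at most 0.03 on the log2 scale. They moved by over 1.5 times with the deposited FPKM at a pseudocount of 1 (356 higher, 373 lower), with no filter (1197 and 946), at a ratio of 1.5 (1736 and 1736) or 3 (192 and 201), and with the whole interval beyond 2 (468 and 418), each a looser or stricter rule by construction. Removal of the GC and length trend gave 638 and 584, and leaving out the cell cycle lists gave 718 and 569. Of 41 lists, 31 kept their side of the random range under all alternatives run for them, up to 12, among them the mitosis, replication, cholesterol, lysosome, ATF4, NRF2 and nuclear respiratory lists, and no list that stood apart changed sign. Among lists within the range, the sign turned for ER chaperones with the GC and length trend removed (0.03), for gluconeogenesis and urea cycle (0.14), glycolysis (0.07) and the BCL2 family (-0.04) at 5 CPM, and for plasma proteins, oncofetal markers, glycolysis and p53 targets with list means. It turned for liver transcription factors, whose median was 0.00, under 5 alternatives, for p53 targets with upper-quartile factors, and for the BCL2 family without the member that moved most. The mesenchymal list fell within the range with no filter (median 0.41, percentile 97.1). The other changes put lists outside it. With FPKM at a pseudocount of 1 these were fatty acid oxidation (-0.27), ferroptosis (0.24) and xenobiotic metabolism (0.25), and at 0.1 xenobiotic metabolism (0.29). With no filter they were ferroptosis (0.29) and histones (-0.66), and at 5 CPM fatty acid oxidation (-0.32), ferroptosis (0.27) and histones (-0.43). With list means they were ferroptosis (0.28), p53 (0.28), the BCL2 family (0.27), histones (-0.47), xenobiotic metabolism (0.59), the sigma and cholinergic list (0.53) and gluconeogenesis and urea cycle (-0.44). Without the member that moved most it was fatty acid oxidation (-0.32), and against unmatched random lists xenobiotic metabolism (0.30). With the GC and length trend removed they were ferroptosis (0.33), xenobiotic metabolism (0.43), the sigma and cholinergic list (0.48), gluconeogenesis and urea cycle (-0.39) and ribosomal proteins (0.26). The cause of these list changes was not tested. Histones and mitochondrially encoded genes had GC values for too few members, so that check is void for them. Depth limits only low genes, since 3 counts are under 0.08 CPM. The spread between cultures, which was not measured, limits the rest.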

Other observations

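The 7 lists named first, the removal of the GC and length trend and the sums over gene copies were chosen only after the ratios of genes and lists had been seen, so the lists are not independent evidence. FOXO target genes were higher in the homochlorcyclizine library, with 10 of 25 measured genes at least 2-fold higher, none 2-fold lower and a median log2 ratio of 0.54 above all 10000 random lists. TP53INP1 was 4.64-fold higher (95% counting interval 4.38 to 4.92). Clock genes went both ways, with 6 of 17 at least 2-fold higher and 1 lower. Their median of 0.03 lay within the random lists at percentile 62.4, and their mean was 0.58. BHLHE41 was 6.82-fold higher (4.91 to 9.70) and PER3 3.75-fold (2.44 to 5.96), while PER2, chosen after its values were seen, had a ratio of 0.329 (0.306 to 0.353). All 31 proteasome subunits were below a ratio of 1 and none passed 2-fold, with PSMC1 and PSMC3 the lowest at ratios of 0.573 and 0.574. Their median of -0.53 lay below all random lists. It was -0.35 with the GC and length trend removed, still below all random lists. Of 21 amino acid breakdown enzymes 17 were below a ratio of 1, with a median of -0.54 at percentile 0.01, whereas CTH, which makes cysteine from cystathionine, was 2.29-fold higher (2.11 to 2.49). Of 14 alcohol and retinol dehydrogenase genes 3 were 2-fold lower, with ADH6 at a ratio of 0.173 (0.125 to 0.234), and 1, DHRS3, was 2-fold higher, with a median of -0.45 at percentile 0.40. The tubulins split, with 3 of 15 at least 2-fold higher, among them TUBA1A and TUBB2B, and 3 lower, among them TUBA1B and TUBB4B. Their median of -0.32 lay within the random lists at percentile 2.54, and their mean was -0.01. TUBA1B was at 797 against 2016 CPM, so TUBA1A gained fewer counts than TUBA1B lost. Of 26 homologous recombination and mismatch repair genes 18 were 2-fold lower and all 26 were below a ratio of 1, with a median of -1.38 below all random lists.

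Genes of DNA replication and mitosis were lower together. The trend of ratios over GC content and transcript length was too small to account for it. Bin medians ran from -0.12 to 0.13 over GC content and from -0.16 to 0.10 over length. Removal of a trend of that size could move the mitosis list's median only a little. That median was -1.71 afterwards (95% bootstrap interval over members of this 1 pair of libraries -1.83 to -1.57), against -1.81 before. The compound itself and a difference in density or growth state between the cultures cannot be told apart, since each group has 1 culture. A candidate explanation is slower proliferation of the treated culture, which these data do not test.

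Most nuclear-encoded respiratory subunits were lower while most mitochondrially encoded mRNAs were higher. Ratios ran from a median of -0.16 in the first of 10 bins of gene length to 0.10 in the last, and respiratory genes are short, so length could account for part. After removal of the GC and length trend the nuclear list's median was -0.36, against -0.46 before. A bootstrap over its members in this 1 pair of libraries gave a 95% interval of -0.50 to -0.25. That interval treats genes as independent and does not cover spread between cultures. The median left after removal argues against that trend as the whole cause. Mitochondrially encoded genes had no GC values, so that check is void for them. The compound and the state of the single cultures remain open, both untested.

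Among the 12353 genes with a mean of at least 1 CPM, the highest and the lowest ratio belong to genes with near-identical copies. For LOC102724560 the summed counts with CBS had a log2 ratio of -0.030 (-0.11 to 0.05), which is consistent with reads of one gene being split differently between the copies in the 2 libraries. For SULT1A4 the sum with SULT1A3 kept a log2 ratio of -1.91 (-2.17 to -1.67), which argues against a split between these copies as the whole cause, although SULT1A3 itself moved the other way and may have taken part of the reads. The sum covers these copies only, and the aligner and counting program are not known. A split with other similar genes therefore stays open. BOLA2B, chosen after its values were seen, had 349 counts against 21, while its copy BOLA2 had 0 counts in both libraries and BOLA2-SMG1P6, looked up with them, had 156 against 187. No biological explanation was tested for these genes.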
